A study of Mus musculus with 11 samples.

How the data were processed

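Total RNA of primary mouse microglia was measured on Illumina bead arrays, with 1 array for each of 11 samples. The cells came from mixed glial cultures of newborn cerebral cortex and were detached by shaking, to a purity that the labels put above 98%. Per the labels, RNA was extracted with Trizol, copied from an oligo-dT primer and amplified into biotin-labelled cRNA, a route that starts at the 3' end of each transcript. The groups were WT at 6 h (n = 3), WT at 12 h (n = 3), KO at 6 h (n = 3) and KO at 12 h (n = 2), taken from the sample labels. Replicate 2 of KO at 12 h is not used here, because the labels state that usable data came from 2 replicates of that group.

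The deposited table of raw values held, per the file headers, the intensity of each probe, which is mean bead brightness without normalization or background correction, and a detection p-value of each probe against the negative control beads of the same array. The submitters' processing notes name BeadStudio 3.4. The authors also deposited processed values, which were checked to be a score per array, the z-score of the log intensity of that array (largest difference from a recomputed z-score 5e-08, within a tolerance of 1e-06). The log base cannot be told from such scores. The per-array medians of these scores lay between −0.487 and −0.450. The genome build of the probe coordinates is not given in the sources used here. No value of a sample outside the series was found (0 values).

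Intensities were processed with limma 3.58.1 in R 4.3.3. The function neqc corrected the background with a normal and exponential model, whose negative control mean and SD were inferred from the detection p-values. It added an offset of 16, quantile normalized the arrays and took log2. Probes with a detection p under 0.01 on at least 2 arrays were kept, 11231 in all, and each gene was represented by its kept probe with the highest mean, which gave 8406 genes. Symbols were updated through the gene identifiers of the file and the RefSeq gene table of the mouse assembly GRCm38.p6, used for names and for gene order. By this route 23681 probes matched, 4172 of them under an updated symbol, and 2016 probes kept the symbol of the file. A probe was called above background on an array at a detection p under 0.01. The lowest log2 value detected on an array was taken as its detection floor.

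A linear model with 4 group means over the 11 arrays was fitted with limma and moderated by eBayes. The contrasts were KO minus WT at 6 h, at 12 h and averaged, 12 h minus 6 h in WT and in KO, and the difference of the KO effects. P-values were adjusted by the method of Benjamini and Hochberg within each contrast, and a gene passed at an adjusted p under 0.05. An error given after a log2 fold change is the SE of the fit. Because the labels do not say that replicates were separate cultures, p-values measure only the spread between these samples. Fixed lists of genes were tested with camera of limma at a preset inter-gene correlation of 0.01 where at least 5 members were measured, 21 lists in all, with the estimated correlation and fry as alternatives. Marker lists of neurons, fibroblasts, endothelium, neutrophils, lymphocytes and monocytes, and the IL-12 family, were too short for that test and are given as counts. The threshold, filter, contrasts, lists and alternatives were chosen before the data were examined, except where stated.

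The genes named were set by a rule. For KO against WT at each time it took Tlr2, the measured IL-12 family, the 8 largest rises and 8 largest falls among genes past the threshold whose arrays did not overlap, and the 2 members of each list with the smallest p in each direction among those past the threshold, or else the 1 member with the smallest p. For the time comparisons and the difference of the KO effects it took 5 rises and 5 falls with up to 2 members of each list, and it passed over gene models without an approved-style symbol. The values of all these genes were computed. After they had been seen, the text was limited to 1 gene per list, in each direction at 12 h, for KO against WT at 12 h and for time in KO, and not every gene of the rule is described. Of 206 named genes 52 had at least 2 kept probes, and these lay over 0.5 log2 from 0 in both directions for 12 genes at 6 h and 15 at 12 h.

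The 3' bias index compared probes of the same transcript at least 200 nt apart. It was defined after such pairs had been seen to differ between arrays, and group differences in it were tested by exact two-sided permutation. The fit with this index as a covariate, and the fit of the WT arrays with KO 6 h replicate 2, were therefore also added after the data had been seen.

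The alternatives were no background correction, an offset of 50, scaling to a common median in place of quantile normalization, the authors' values, no filter and a stricter filter, the mean of all probes of a gene, array weights, eBayes with trend and robust settings, a required 2-fold change, only the 2 groups compared, a replicate block, and leaving out each array in turn. A block for the chip was not run, since the files give no chip identifiers. The pipeline was tested on simulated data of 8406 genes, in which 100 genes were changed 2-fold and 100 were changed 4-fold. It recovered 53 and 93 of them at 6 h, 37 and 90 at 12 h, 52 and 94 for time in WT, and 41 and 90 for time in KO, with 5, 9, 9 and 7 false calls. With 1 raised list among 21, camera called that list and 0 others.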

Results

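Microglia, the resident macrophages of the brain, were grown from the cerebral cortex of newborn wild-type (WT) and TLR2-knockout (KO) mice and exposed for 6 or 12 h to heat-inactivated Staphylococcus aureus USA300, a methicillin-resistant strain. TLR2 is the receptor that senses bacterial lipoproteins, and the series asks how it acts together with TLR9, a sensor of bacterial DNA, on the IL-12 family of cytokines. Messenger RNA was measured on Illumina bead arrays, 1 array per sample. There were 3 WT and 3 KO arrays at 6 h, and 3 WT and 2 KO arrays at 12 h, where KO replicates 1 and 3 were used and replicate 2 is not analysed here. Every sample had met the bacteria, so no comparison measures induction. Between 33.6% and 38.9% of the probes were detected on an array, with a mean intensity of 427 to 853, and the number of arrays limits the precision. The labels do not say whether the replicates of a group were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

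Arrays differed in how evenly transcripts were covered. A 3' bias index was taken over 1109 transcripts with probes at least 200 nt apart, as the median log2 signal of the probe nearest the 3' end minus that of the probe nearest the 5' end, centred over the arrays. The index was −0.60 ± 0.04 (SD, n = 3) in WT at 6 h, −0.45 ± 0.10 (n = 3) in WT at 12 h, 0.24 ± 0.55 (n = 3) in KO at 6 h and 1.09 ± 0.33 (n = 2) in KO at 12 h. KO 6 h replicates 1, 2 and 3 had 0.18, −0.27 and 0.82. KO arrays lay 1.11 above WT arrays (exact two-sided permutation test over 462 splits, p = 0.00216). The difference was 0.84 at 6 h and 1.54 at 12 h, each with an exact permutation p of 0.1, the smallest that these group sizes allow. Across genes, arrays of one WT group correlated at r = 0.970 to 0.994, the KO arrays at 6 h at 0.910 to 0.974, and WT with KO arrays at 0.781 to 0.944. The main axis of variation (63.0% of variance) followed the index (r = 0.982). Genes were therefore also tested at 6 h in a fit with this index as a covariate. A second fit used the 6 WT arrays and KO 6 h replicate 2, the KO array with the lowest index. Counts within gene lists are from the first. Both fits were added after the index was seen, and the second assumes that a lone KO array varies like WT arrays.

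**Figure D1:**
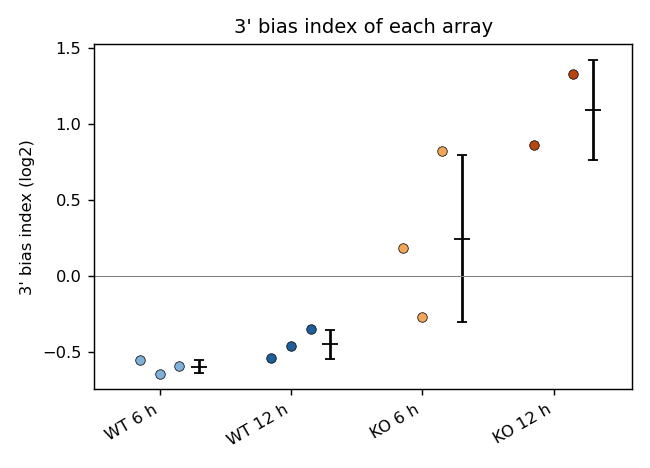
3' bias index (log2) of each of the 11 arrays by group, with the mean and SD of each group beside the points. The WT arrays lie between −0.64 and −0.35, and the KO arrays between −0.27 and 1.33.

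Tlr2 mRNA was abundant in WT microglia and was not above background on any of the 5 KO arrays, which checks the genotype labels as far as the probe can. The mean normalized log2 intensity was 14.96 ± 0.27 (SD, n = 3) in WT at 6 h and 14.24 ± 0.02 (n = 3) in WT at 12 h, against 4.74 ± 0.02 (n = 3) and 4.87 ± 0.03 (n = 2) in KO. Tlr2 was at least 465-fold lower in KO at 6 h (adjusted p = 2.76e-11) and at least 285-fold lower at 12 h (adjusted p = 2.27e-10). With all 11 arrays, a called change between 2 groups of which 1 has no array above background is given as at least the fold between the mean of the bright group and the detection floor of the arrays of the dim group. For such genes, values from other fits and differences between KO effects are fitted values and no bounds. The 1 Tlr2 probe lies on chromosome 3 at 83640551 to 83640600 in the coordinates of the file, whose genome build is not given in the sources used here, and starts at nt 2607 of the transcript. Whether it lies in the deleted part is not given in the sources used here.

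The comparison of KO with WT at 6 h asks which mRNAs differ in the absence of TLR2 after exposure to the bacteria. KO microglia had less mRNA of Nos2, the inducible nitric oxide synthase (log2 fold change −4.59 ± 0.38 SE, above background on 1 of 3 KO arrays), of Lcn2, which binds bacterial siderophores (−2.66 ± 0.22), of the anti-inflammatory cytokine Il10 (−2.18 ± 0.19), of Cd300lf, an inhibitory receptor of myeloid cells (−4.36 ± 0.32, above background on 1 of 3 KO arrays), and of H2-DMa, which loads peptides onto MHC class II (−2.59 ± 0.20, above background on 2 of 3 KO arrays). They had more mRNA of Cxcl9, a chemokine for T cells (3.59 ± 0.19), and of Mbp, a structural protein of myelin (4.40 ± 0.21). The probe used for Mbp starts at nt 2211, and a probe at nt 4610 of another transcript record gave −0.28. Bcas1, a gene of early myelinating oligodendrocytes, was at least 8.49-fold higher, Cldn11, the claudin of myelin, at least 8.45-fold, Pcna, the sliding clamp of DNA polymerases, at least 6.74-fold and Gap43, a growth cone protein, at least 6.19-fold. Tmem251 was also among the largest rises (3.67 ± 0.28). Each of these 12 genes passed the test in all 3 fits, with adjusted p of 2.32e-05 or lower with all 11 arrays, and the 3 KO arrays did not overlap the 3 WT arrays.

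Of 8406 genes tested at 6 h with limma, 2876 passed adjusted p 0.05, 1786 higher and 1090 lower in KO. With the 3' bias index as a covariate 1419 genes passed (756 higher, 663 lower), and with KO 6 h replicate 2 as the KO array 1466 passed (857 higher, 609 lower). Array weights gave 4680 genes, and a required 2-fold change 1602. The same direction was called in all 3 fits for 1026 genes, 611 higher and 415 lower in KO. Some of the largest falls moved with the index. Hspa8, a constitutive chaperone, went from −6.34 ± 1.83 to −0.71 with the covariate (adjusted p = 0.823) and −0.41 with KO 6 h replicate 2 (adjusted p = 0.317). Csf3, the granulocyte growth factor, went from −4.44 ± 1.22 to −0.67 (adjusted p = 0.738) and −0.49 (adjusted p = 0.164). Thbs1 (−5.61 ± 1.03), Tnfrsf1b (−4.94 ± 0.97) and Eef2 (−4.88 ± 1.0) missed the threshold with the covariate, at −2.54, −2.03 and −2.13 (adjusted p of 0.129, 0.185 and 0.219), and passed with KO 6 h replicate 2 at −2.31, −1.83 and −1.69. These 5 genes were above background on 1 of 3 KO arrays. Hspa8 missed the threshold without WT 6 h replicate 1 or 3 or KO 6 h replicate 1 or 3 (−6.34 to −4.57), and Csf3 without WT 6 h replicate 3 or KO 6 h replicate 1 or 3 (−4.38 to −3.33). The median log2 fold change of all genes was 0.09, and 0.31 when arrays were scaled to a common median in place of quantile normalization, which moved the share of calls that were higher in KO from 62.1% to 77.5%.

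**Figure D2:**
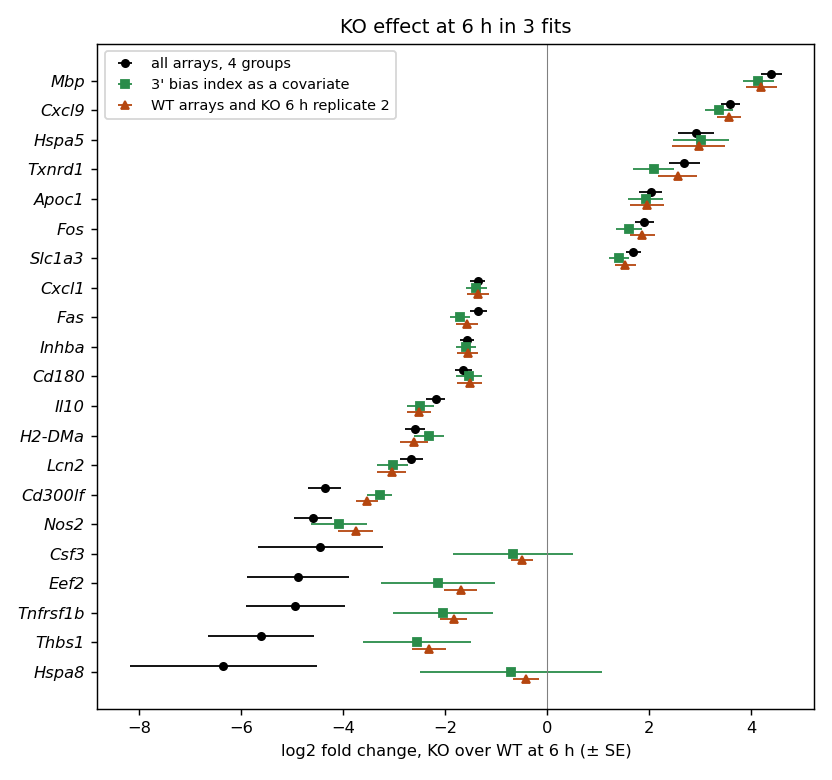
Log2 fold change (x axis, KO over WT at 6 h, bars are SE) of 21 genes in the fit of all 11 arrays, with the 3' bias index as a covariate, and with the 6 WT arrays and KO 6 h replicate 2. Mbp and Cxcl9 stay above 3 and Nos2 and Cd300lf below −3 in each fit, while Hspa8 and Csf3 lie within 1 of 0 in 2 of the 3 fits.

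The IL-12 family, the subject of the series, differed between genotypes at 6 h in 1 of its 4 measured members. Il23a, the p19 subunit of IL-23, was above background on 3 of 3 KO arrays (normalized log2 intensity 6.64 ± 0.28) and on 0 of 3 WT arrays (5.38 ± 0.47) at 6 h, at least 1.53-fold higher in KO (adjusted p = 0.0023, and 0.00113 adjusted over the list alone). It also passed with the index as a covariate (adjusted p = 0.00803) and with KO 6 h replicate 2 (adjusted p = 0.0106). Il12a, the p35 subunit of IL-12, had −0.16 ± 0.23 at 6 h (adjusted p = 0.625). Il27, the p28 subunit of IL-27, had 0.40 ± 0.35 (adjusted p = 0.392), and its partner Ebi3 had −0.07 ± 0.18 (adjusted p = 0.795). With the index as a covariate Il12a had −0.84 ± 0.23 and passed as lower in KO (adjusted p = 0.0344), and with KO 6 h replicate 2 it had −0.62 and missed the threshold (adjusted p = 0.0886). Il27 and Ebi3 passed in neither of these fits (adjusted p of 0.316 and 0.837 with the covariate, 0.757 and 0.962 with KO 6 h replicate 2). Il12b, the p40 subunit that IL-12 and IL-23 share, was not above background on any of the 11 arrays, so this gene could not be compared.

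At 12 h no IL-12 family gene passed the test between KO and WT with all 11 arrays. Il12a had −0.39 ± 0.26 (adjusted p = 0.233), Il27 0.34 ± 0.39 (adjusted p = 0.48) and Ebi3 −0.25 ± 0.20 (adjusted p = 0.337), while Il23a was below background in both genotypes. By limma 0 of the 4 genes passed over all genes or adjusted over the list alone, and 0 had an unadjusted p under 0.05. With the index as a covariate Il12a had −1.64 at 12 h (adjusted p = 0.0848, and 0.0046 adjusted over the list alone). From 6 to 12 h Il27 fell in both genotypes, with −2.24 ± 0.35 in WT (adjusted p = 0.00157) and −2.30 ± 0.39 in KO (adjusted p = 0.00314, and −1.90 with the index as a covariate with adjusted p = 0.0667). Il12a rose in WT by 0.83 ± 0.23 (adjusted p = 0.0279), a call that ended without any 1 of the 6 WT arrays (adjusted p of 0.0535 to 0.0928), and had 0.60 ± 0.26 in KO (adjusted p = 0.11). Ebi3 had 0.52 ± 0.18 in WT (adjusted p = 0.0656, and 0.0202 adjusted over the list alone) and passed with the covariate (adjusted p = 0.0375). Il23a fell in KO, at least 1.46-fold (adjusted p = 0.00176, and 0.0448 with the covariate). The test of the difference in KO effect between the times gave Il23a an adjusted p of 0.0782 over all genes and 0.00395 adjusted over the list alone, against 0.226 and 0.0275 with the covariate. A further Il23a probe, starting at nt 1174 where the probe used starts at nt 746, was not above background on any array.

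**Figure D3:**
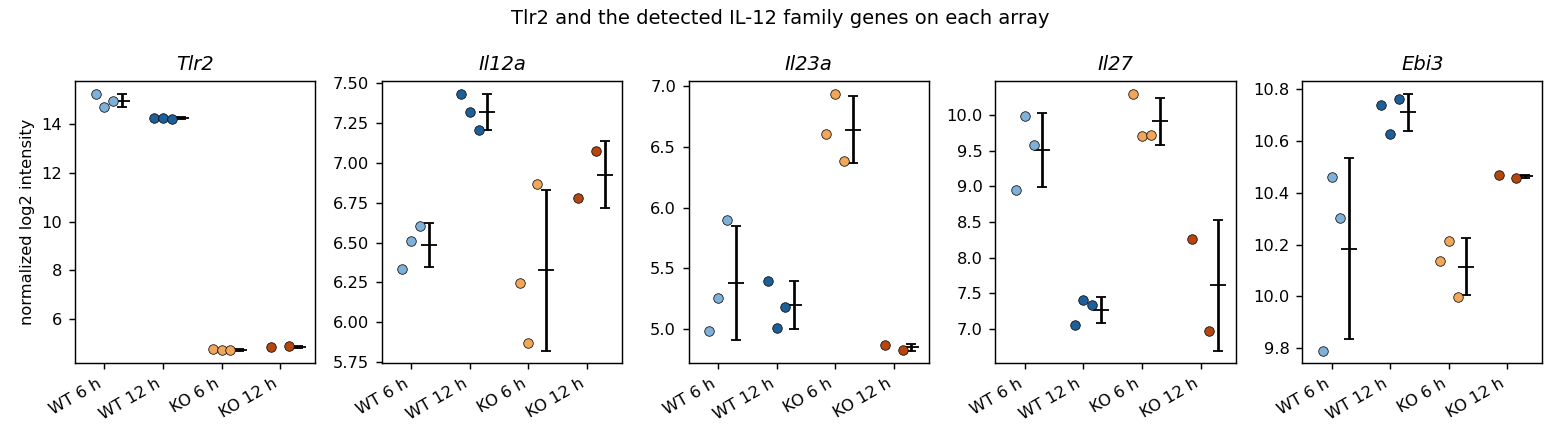
Normalized log2 intensity of Tlr2 and of the 4 detected IL-12 family genes on each of the 11 arrays by group, with the mean and SD of each group beside the points. Tlr2 separates the genotypes, Il23a is highest on the 3 KO arrays at 6 h, and Il27 is lower at 12 h than at 6 h in both genotypes.

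Among receptors and signalling genes at 6 h, the changes went both ways. Cd180, a toll-like receptor homologue of B cells and macrophages, was lower in KO (−1.65 ± 0.17), as was Naip5, a sensor of flagellin (−1.01 ± 0.23), and both passed in all 3 fits. The fungal sensor Clec7a (1.34 ± 0.23) and Clec4d (0.69 ± 0.16) were higher and missed the threshold with the covariate, at 1.06 and 0.50 (adjusted p of 0.0504 and 0.159). Of 20 measured bacterial sensors 3 were higher and 5 lower (3 and 6 adjusted over the list alone), and the covariate fit called 0 higher and 2 lower. In the list of toll-like receptor signalling and NF-kB, 5 of 26 genes were higher and 2 lower (4 and 2 adjusted over the list alone), against 1 and 2 with the covariate. The immediate-early factor Fos was higher (1.91 ± 0.18) and the adaptor Ticam2 lower (−0.93 ± 0.14) in all 3 fits. Rel (1.51 ± 0.28) and Tirap (−0.89 ± 0.25) missed the threshold with the covariate, at 0.76 and −0.23 (adjusted p of 0.128 and 0.617). The probes of Tirap disagreed in sign, and it also missed the threshold with KO 6 h replicate 2 (−0.52, adjusted p = 0.231) and without WT 6 h replicate 2 (−0.76).

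Secreted mediators were split in the same way. Inhba, the activin A subunit (−1.57 ± 0.13), Cxcl1, a chemokine for neutrophils (−1.36 ± 0.14), and Il1rn, the IL-1 receptor antagonist (−0.94 ± 0.17), were lower in KO in all 3 fits. Cxcl13, a chemokine for B cells, was at least 4.13-fold higher in all 3 fits. Il33 was at least 1.63-fold and Il1f6 at least 1.16-fold higher. With the covariate they had 0.51 and 0.74 (adjusted p of 0.175 and 0.0636), Il33 with KO 6 h replicate 2 had 0.72 (adjusted p = 0.0603), and Il1f6 was above background on 2 of 3 KO arrays. Of 23 cytokines outside the IL-12 family 5 were higher and 5 lower (5 and 5 adjusted over the list alone), against 0 and 3 with the covariate. Of 17 chemokines 4 were higher and 4 lower, also when adjusted over the list alone, against 4 and 2 with the covariate, where Ccl6 (−1.77 ± 0.29) had −1.0 (adjusted p = 0.0641). Of 19 negative regulators of inflammation 3 were higher and 4 lower (3 and 6 adjusted over the list alone), and 3 and 3 with the covariate. They included Nfkbib (1.40 ± 0.22), an inhibitor of NF-kB that passed in all 3 fits, and Nfkbie, whose probe at nt 2082 gave 1.31 ± 0.18 and whose probe at nt 645 gave −0.59.

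Of 31 measured antimicrobial and inflammatory effectors 4 were higher and 10 lower in KO at 6 h, also when adjusted over the list alone, against 1 and 10 with the covariate. Ptgs2, the inducible cyclooxygenase, was higher (2.60 ± 0.47) and missed the threshold with the covariate (1.79, adjusted p = 0.0931). Marcksl1 gave 1.91 ± 0.18 with its probe at nt 1249 and −2.80 and −3.45 with those at nt 175 and 255. Of 17 antigen presentation and co-stimulation genes 1 was higher and 7 lower, also when adjusted over the list alone, against 3 and 4 with the covariate. The protease Ctss was higher (1.76 ± 0.25) and the co-stimulatory ligand Cd80 at least 1.89-fold lower, both in all 3 fits. Of 34 type I interferon response genes 4 were higher and 4 lower (3 and 4 adjusted over the list alone), against 2 and 4 with the covariate. Oas2 (−1.26 ± 0.16) and Oasl1 (−1.07 ± 0.19) were lower and the RNA sensor Ifih1 higher (2.44 ± 0.38, above background on 2 of 3 WT arrays) in all 3 fits, while Rtp4 (1.0 ± 0.19) had 0.84 with KO 6 h replicate 2 (adjusted p = 0.053). Camera gave adjusted p of 0.0566 for the effectors, 0.0566 for antigen presentation and 0.0831 for the interferon genes.

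Microglial genes also moved apart. Olfml3, a gene enriched in microglia, was at least 5.48-fold lower in KO at 6 h, and Selplg, the P-selectin ligand, was lower (−1.15 ± 0.17), both in all 3 fits. Cst3 was higher (0.70 ± 0.14) and missed the threshold with the covariate (0.69, adjusted p = 0.051) and with KO 6 h replicate 2 (0.70, adjusted p = 0.0571) at nearly the same size. Csf1r, the receptor that microglia need for survival, gave 1.91 ± 0.16 with its probe at nt 3495 and −3.56 with that at nt 2341. Of 22 microglia identity genes 9 were higher and 4 lower (10 and 5 adjusted over the list alone), against 2 and 3 with the covariate. Of 19 phagocytic and scavenger receptors 5 were higher and 5 lower, also when adjusted over the list alone, against 2 and 3 with the covariate. The scavenger receptor Marco was higher (0.87 ± 0.15) and the Fc receptor Fcgr1 lower (−0.84 ± 0.19) in all 3 fits, while Cd93 (1.33 ± 0.24) had 0.93 with the covariate (adjusted p = 0.0864). Fcgr4 (−0.70 ± 0.15) had −0.80 with the covariate, where it passed, and −0.76 with KO 6 h replicate 2 (adjusted p = 0.0541). Of 25 lysosome genes 6 were higher and 1 lower (5 and 1 adjusted over the list alone), against 1 and 1 with the covariate. Npc2, a cholesterol carrier of the lysosome, was higher (1.16 ± 0.15) and the protease Ctsk lower (−0.91 ± 0.14) in all 3 fits, and Ctsz (0.97 ± 0.18) had 0.71 with the covariate (adjusted p = 0.0787) and 0.80 with KO 6 h replicate 2 (adjusted p = 0.0531).

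Hspa5, the chaperone of the endoplasmic reticulum, was higher in KO at 6 h (2.92 ± 0.36, above background on 2 of 3 WT arrays), as were Txnrd1, a thioredoxin reductase (2.69 ± 0.30), Apoc1, an apolipoprotein (2.03 ± 0.22), the desaturase Scd1 (1.97 ± 0.23) and Ndufb5 of respiratory complex I (2.16 ± 0.22), each in all 3 fits. Of 21 integrated stress and unfolded protein response genes 11 were higher and 3 lower (12 and 4 adjusted over the list alone), against 6 and 2 with the covariate. They included Ppp1r15a (1.20 ± 0.18, all 3 fits), Xbp1 (−0.67 ± 0.14, and −0.67 with KO 6 h replicate 2 with adjusted p = 0.0616) and Phgdh (−2.26 ± 0.41, above background on 1 of 3 KO arrays, and −1.14 with the covariate with adjusted p = 0.12). Of 18 oxidative stress genes 6 were higher and 1 lower, also when adjusted over the list alone, against 4 and 0 with the covariate. Me1 was higher in all 3 fits (1.91 ± 0.23) and Nqo1 went from −1.58 ± 0.33 to −0.43 with the covariate (adjusted p = 0.244), was above background on 2 of 3 KO arrays, and passed with KO 6 h replicate 2 (adjusted p = 0.0274). Of 14 cholesterol synthesis genes 8 were higher and 1 lower, also when adjusted over the list alone, against 2 and 0 with the covariate. Idi1, an isomerase of that pathway, was at least 1.70-fold higher and Msmo1, which demethylates sterols, higher by 1.29 ± 0.17, both in all 3 fits. Nsdhl gave −1.62 ± 0.48, −1.21 and −1.47 with 3 probes and 0.74 with the probe at nt 1881. Its call ended with the covariate (−0.24, adjusted p = 0.781), with KO 6 h replicate 2 (−0.16, adjusted p = 0.727) and without any 1 of 5 of the 6 arrays at 6 h, all but KO replicate 2 (−1.67 to −1.24).

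Of 16 genes of cholesterol efflux and lipid handling 5 were higher and 3 lower in KO at 6 h (7 and 3 adjusted over the list alone), against 4 and 1 with the covariate. Lpcat3 (−1.11 ± 0.30) and Apoc2 (−1.77 ± 0.55) missed the threshold there, at −0.11 and 0.22, and with KO 6 h replicate 2, at −0.70 and −0.53 (adjusted p of 0.0502 and 0.317). Further probes gave 0.80 for Lpcat3 and 0.36 for Apoc2. The call of Apoc2 also ended without WT 6 h replicate 2 or 3 or KO 6 h replicate 1 or 3 (−1.80 to −1.13). Of 24 respiratory chain genes 5 were higher and 0 lower, also when adjusted over the list alone, against 4 and 0 with the covariate, and Cox7a2 was higher (2.01 ± 0.23) in all 3 fits. Of 19 glycolysis and hypoxia genes 2 were higher and 3 lower (2 and 2 adjusted over the list alone), against 1 and 1 with the covariate. Adm, a vasodilator peptide induced by hypoxia, was at least 2.95-fold higher and Hk1, a hexokinase, at least 2.20-fold lower in all 3 fits. Vegfa (1.34 ± 0.27) and Ldha (−0.44 ± 0.14) missed the threshold with the covariate at 0.86 and −0.60 (adjusted p of 0.145 and 0.0665). The call of Ldha also ended with KO 6 h replicate 2 (−0.54, adjusted p = 0.117) and with any 1 of 7 arrays left out (−0.44 to −0.38). Of 19 cell cycle genes 4 were higher and 5 lower (4 and 6 adjusted over the list alone), against 3 and 3 with the covariate. Ccnd1 was higher (1.15 ± 0.18, and −0.32 with a probe at nt 2463) and the mitotic kinase Plk1 lower (−1.72 ± 0.23, above background on 1 of 3 KO arrays) in all 3 fits. Cdca8 was at least 1.25-fold lower, and had −0.84 with the covariate (adjusted p = 0.125) and −0.94 with KO 6 h replicate 2 (adjusted p = 0.0933). Of 21 cell death and survival genes 4 were higher and 3 lower, also when adjusted over the list alone, against 0 and 4 with the covariate. The death receptor Fas was lower (−1.35 ± 0.16, and −1.77 with a probe at nt 394) in all 3 fits. Birc3 was at least 2.36-fold and Bcl2 at least 1.57-fold higher, with 0.83 and 0.63 with the covariate (adjusted p of 0.109 and 0.212). The call of Bcl2 ended with KO 6 h replicate 2 (0.44, adjusted p = 0.329) and without WT 6 h replicate 1 or KO 6 h replicate 1 (adjusted p of 0.0576 to 0.0761). The 2 probes of Mlkl gave −0.69 ± 0.15 and 1.56. The first had −0.84 with the covariate, where it passed, and −0.72 with KO 6 h replicate 2 (adjusted p = 0.0513).

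Markers of other brain cell types differed between the genotypes at 6 h. Of 7 measured oligodendrocyte lineage markers 4 were higher and 1 lower in KO, also when adjusted over the list alone. Olig1, a transcription factor of that lineage, was higher (2.88 ± 0.14) with Mbp and the growth factor receptor Pdgfra (at least 4.61-fold), and these 3 passed in all 3 fits. Cspg4 was at least 1.26-fold lower, and had −0.73 with the covariate (adjusted p = 0.0941) and −0.88 with KO 6 h replicate 2 (adjusted p = 0.058). Camera called the list (adjusted p = 0.035, and adjusted p = 0.228 with an estimated correlation), with 0.000346 in the covariate fit (adjusted p = 0.174 with an estimated correlation) and 0.000984 with KO 6 h replicate 2 (adjusted p = 0.375 with an estimated correlation). The fit with KO 6 h replicate 2 also called cholesterol synthesis (0.0463, and adjusted p = 0.375 with an estimated correlation). With all 11 arrays the other 20 lists had adjusted p of 0.0566 to 0.872. A replicate block left 0 lists called at 6 h. Without KO 6 h replicate 2 camera called 0 lists (0.0703 for this one), without WT 6 h replicate 1 it called 2, and without KO 12 h replicate 1 or 3 it called 4. Among the lists not called, the median, the mean and the direction of camera differed in sign for bacterial sensors, toll-like receptor signalling, cytokines, chemokines, microglia identity, phagocytic receptors and the lysosome. All 3 measured neuron markers were higher, among them Map2 (1.84 ± 0.20) and Dcx (1.30 ± 0.17), which passed in all 3 fits, and 2 of the 3 passed with the covariate.

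Markers of further cell types were lower or mixed. Of 6 astrocyte markers 1 was higher and 4 lower (2 and 4 adjusted over the list alone), against 1 and 3 with the covariate. The gap junction gene Gja1 was at least 4.75-fold and the water channel Aqp4 at least 2.47-fold lower, while the glutamate transporter Slc1a3 was higher (1.69 ± 0.15), in all 3 fits. Both measured fibroblast and meningeal markers were lower in all 3 fits, Dcn at least 1.82-fold and Acta2 by −1.52 ± 0.23. Of 3 endothelial markers Flt1 was higher (1.32 ± 0.15) and Vwf lower (−1.51 ± 0.16) in all 3 fits. The neutrophil marker S100a8 was lower (−0.51 ± 0.17), 1 of 2 in its list, missed the threshold with the covariate (−0.50, adjusted p = 0.205) and with KO 6 h replicate 2 (−0.50, adjusted p = 0.233), and lost its call with any 1 of 10 arrays left out (−0.52 to −0.39). Of 4 monocyte and peripheral macrophage markers Ly6c1 (−0.94 ± 0.22) and F13a1 (−0.91 ± 0.26) were lower and Lyz2 higher (0.60 ± 0.17), of which F13a1 passed in all 3 fits. Ly6c1 had −0.62 with the covariate (adjusted p = 0.211) and −0.83 with KO 6 h replicate 2 (adjusted p = 0.0599). The probe of Lyz2 at nt 133 gave −1.15, and its call ended with the covariate (0.66, adjusted p = 0.102), with KO 6 h replicate 2 (0.71, adjusted p = 0.0924) and without WT 6 h replicate 2 (0.46). The call of F13a1 ended without WT 6 h replicate 1 or 3 or KO 6 h replicate 1 or 2 (−0.88 to −0.68). The 1 measured lymphocyte marker, Lck, had 0.67 ± 0.32 (adjusted p = 0.132), and passed without WT 6 h replicate 2 (1.01) or KO 6 h replicate 2 (0.92). Except for astrocytes, the counts of these marker lists were the same when adjusted over the list alone.

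**Figure D4:**
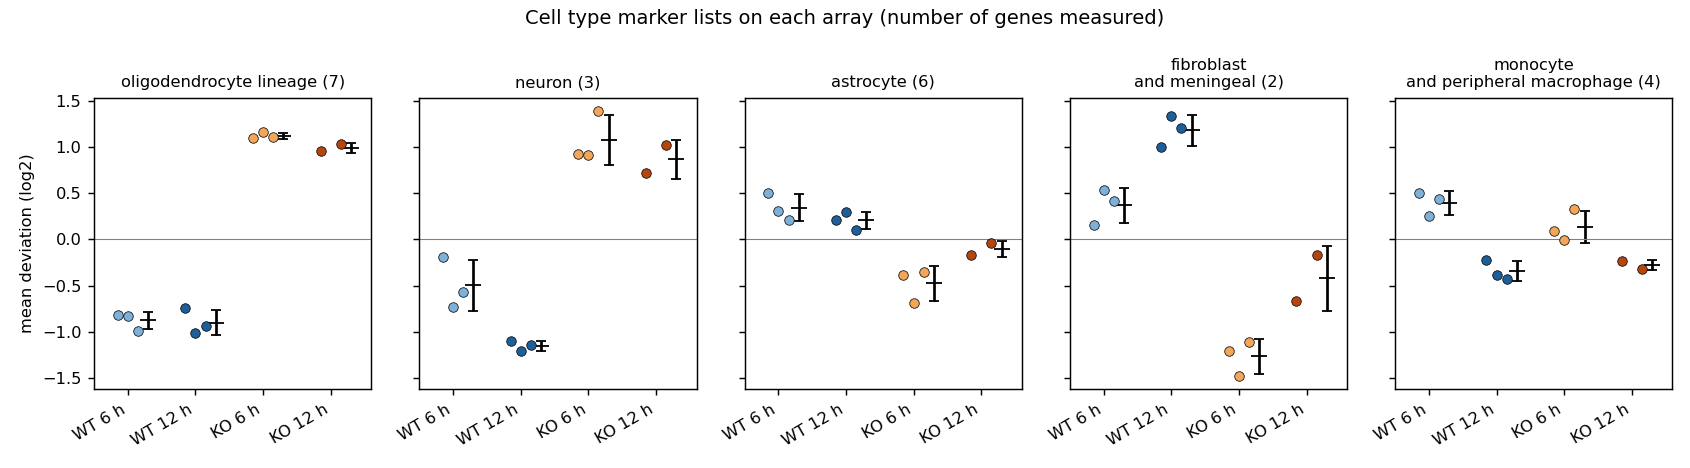
Mean deviation of each marker list from its mean over all 11 arrays (log2) on each array by group, with the mean and SD of each group beside the points and the number of genes measured in brackets. The oligodendrocyte list lies between 0.95 and 1.16 on the 5 KO arrays and between −1.02 and −0.75 on the 6 WT arrays, while the astrocyte and fibroblast lists are lower on KO arrays.

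At 12 h the same comparison gave higher Mbp (4.08 ± 0.23, and −0.23 with the probe at nt 4610), Olig1 (3.19 ± 0.15), Cxcl9 (3.32 ± 0.21) and Flt1 (1.88 ± 0.17, above background on 1 of 3 WT arrays) in KO, and lower Cxcl1 (−2.23 ± 0.16), Arg1, the arginase of alternatively activated macrophages (−2.19 ± 0.19), Dcn (−2.44 ± 0.22) and Gja1 (−2.08 ± 0.27). Olfml3 was at least 3.36-fold lower and the glutamate transporter Slc1a1 at least 7.08-fold higher. Each of these 10 genes also passed with the index as a covariate, as did Slc1a3 (2.23 ± 0.17), Bcas1 (at least 6.82-fold higher), Stmn1, a tubulin-binding protein (at least 5.05-fold higher), and Nqo1 (at least 12.9-fold lower). Of 8406 genes 3878 passed by limma, 2479 higher and 1399 lower, with n = 3 WT and n = 2 KO arrays, and 68 passed with the covariate (33 higher, 35 lower). A required 2-fold change left 2507. Without KO 12 h replicate 3, the array with the highest index, 1715 genes passed. The median log2 fold change of all genes was 0.27, and 0.55 with scaling to a common median.

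Of the 7 falls named by size at 12 h besides Tlr2, 6 turned to values above 0 with the covariate. Hspa8, at least 404-fold lower in KO, had 0.58 (adjusted p = 0.96), Msn (−7.35 ± 1.40) had 0.83, Ifit3b (−6.76 ± 1.33) 0.83, Pld3 (−6.74 ± 1.16) 0.02, Eif4g2 (−6.28 ± 1.36) 1.15 and the glycolytic enzyme Eno1 (−6.26 ± 1.17) 0.29, while Thbs1, at least 90.3-fold lower, had −2.22 (adjusted p = 0.661). Msn, Ifit3b and Eno1 were above background on 1 of 2 KO arrays. A probe of Eif4g2 nearer the 3' end gave 2.99. Among the largest rises, Gap43 was at least 7.01-fold higher, Tmem251 had 3.61 ± 0.31 and Vxn 3.33 ± 0.31, and these had 1.79, 2.65 and 2.33 with the covariate (adjusted p of 0.0705, 0.0803 and 0.119).

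The gene lists at 12 h held many calls of which few were left with the covariate. Of 19 glycolysis and hypoxia genes 2 were higher and 9 lower (2 and 10 adjusted over the list alone), led by Eno1 and by Hk1 (at least 1.86-fold lower), and Adm was at least 1.82-fold higher (−0.18 with the covariate). This was the 1 list that camera called (adjusted p = 0.0296, and adjusted p = 0.219 with an estimated correlation), with 0 calls among its genes and a camera adjusted p of 0.566 with the covariate. Without WT 12 h replicate 1 camera called 0 lists (0.0546 for this one), and without KO 12 h replicate 3 it called 3. The other lists had adjusted p of 0.0911 to 0.984. Of 34 type I interferon genes 15 were higher and 6 lower (19 and 7 adjusted over the list alone), among them Ifnb1 itself (at least 3-fold higher) and Isg15 (−2.89 ± 0.57, 0.01 with the covariate). Of 14 cholesterol synthesis genes 10 were higher and 1 lower, also when adjusted over the list alone. The covariate fit called 0 genes of either list. The oligodendrocyte list had 4 genes higher and 1 lower, also when adjusted over the list alone, and 3 higher with the covariate. Its camera adjusted p was 0.0911 with all 11 arrays and 7.18e-07 with the covariate (adjusted p = 0.0537 with an estimated correlation).

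In the other immune lists at 12 h, the calls with the covariate came to Cxcl9 and Cxcl1 among the chemokines, 3 effectors, which were Arg1, Lcn2 and Ptx3, and Olfml3. Without it, 6 of 20 bacterial sensors were higher and 3 lower, including Clec7a (1.31 ± 0.25) and Tlr8 (at least 5.22-fold lower, 1.39 with the covariate, and adjusted p = 0.0524 without KO 12 h replicate 3), and 10 of 26 signalling genes were higher and 4 lower, including Rel (2.67 ± 0.31) and Ticam2 (−1.27 ± 0.16). Of 19 negative regulators 6 were higher and 5 lower, including Cish, a cytokine-induced inhibitor of STAT signalling (1.80 ± 0.18), and Zc3h12a (−0.77 ± 0.17). Of 23 cytokines 9 were higher and 6 lower, including Il15 (2.11 ± 0.21, −1.81 with a probe at nt 90) and Tnfsf9 (−2.56 ± 0.51, above background on 1 of 2 KO arrays, and 0.10 with the covariate). Mfge8 lost its call without KO 12 h replicate 1 (−0.71) or 3 (−0.79). Chemokines had 6 higher and 3 lower of 17, antigen presentation 5 and 8 of 17 with Cd40 (1.17 ± 0.15) and H2-DMa (at least 2.81-fold lower), and effectors 7 and 10 of 31. Microglia identity had 9 and 7 of 22, and phagocytic receptors 6 and 1 of 19 with Gas6 (1.27 ± 0.21) and Mfge8 (−0.75 ± 0.21, and 0.05 with the covariate). Adjusted over the list alone, higher and lower counts were 6 and 4 for sensors, 6 and 6 for negative regulators, 5 and 9 for antigen presentation, 8 and 10 for effectors and 10 and 7 for microglia identity, and unchanged for signalling, cytokines, chemokines and phagocytic receptors. The probes of Marcksl1, Csf1r and Cd40 disagreed in sign. Among the lists not called, the median, the mean and the direction of camera differed in sign for sensors, signalling, negative regulators, cytokines, microglia identity, the respiratory chain and lipid handling.

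The lists of metabolism, growth and survival at 12 h were likewise mixed. Higher and lower counts were 5 and 2 of 24 for the respiratory chain, with Ndufb5 (2.18 ± 0.25) and Atp5o (−2.88 ± 0.69), and 5 and 5 of 16 for lipid handling, with Scd1 (at least 5.05-fold higher) and Lpcat3 (−2.38 ± 0.34, and −0.07 with a probe at nt 1466). They were 7 and 3 of 18 for oxidative stress, with Txnrd1 (3.13 ± 0.34), and 8 and 4 of 21 for the stress and unfolded protein response, with Ppp1r15a (1.18 ± 0.20) and Sesn2 (at least 1.22-fold lower). They were 8 and 4 of 19 for the cell cycle, with Pcna (3.04 ± 0.25, above background on 1 of 3 WT arrays) and Tyms (−1.55 ± 0.34), 7 and 3 of 25 for the lysosome, with Npc2 (1.08 ± 0.17) and Ctsk (−0.96 ± 0.16), and 8 and 2 of 21 for cell death, with Birc3 (2.04 ± 0.39) and Bcl2l1 (at least 8.68-fold lower). Adjusted over the list alone they were 6 and 5 for lipid handling, 9 and 4 for the stress response, 10 and 4 for the cell cycle and 6 and 3 for the lysosome, and the same for the other 3. In these 7 lists the covariate fit called 1 gene, Nqo1. There Atp5o (1.01), Tyms (0.14) and Bcl2l1 (0.997) turned to values above 0, as did Nsdhl (0.59), and Birc3 had 0.06. Without KO 12 h replicate 3 the calls of Atp5o (−2.21), Tyms (−1.02), Nsdhl (−1.88) and Bcl2l1 (adjusted p = 0.0602) ended, and that of Bcl2l1 also without KO 12 h replicate 1 (adjusted p = 0.0501). The cholesterol synthesis genes Sqle (1.63 ± 0.24) and Nsdhl (−1.95 ± 0.53) had probes of opposite sign.

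Among the other cell type markers at 12 h, 3 of 3 neuron markers were higher, including Map2 (2.39 ± 0.22), and both fibroblast markers were lower. Astrocyte markers had 2 higher and 3 lower of 6, and endothelial markers 2 higher and 1 lower of 3, with Vwf at −0.60 ± 0.18, which missed the threshold without WT 12 h replicate 2 (−0.53) or KO 12 h replicate 1 (−0.54) or 3 (−0.66). Cspg4 passed as lower (adjusted p = 0.0359) with 0 of 2 KO and 2 of 3 WT arrays above background, too faint for a fold (0.03 with the covariate), and missed the threshold with any 1 of 5 arrays left out (adjusted p of 0.0518 to 0.13). Mrc1, a mannose receptor of macrophages, was higher (1.28 ± 0.23) and Ly6c1 lower (−1.52 ± 0.25), each 1 of 4 in the monocyte list. Lck was higher (1.29 ± 0.36, and 1.13 without KO 12 h replicate 3 with adjusted p = 0.115), and S100a8 had −0.29 ± 0.19 (adjusted p = 0.218). With the covariate 0 neuron, 1 fibroblast, 3 astrocyte and 1 endothelial marker passed, the fibroblast one being Dcn.

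Averaged over both times, 4696 of 8406 genes differed between KO and WT by limma, 2943 higher and 1753 lower with 5 KO and 6 WT arrays, and 513 passed with the index as a covariate (285 higher, 228 lower). A required 2-fold change left 2046. The KO effects at 6 h and 12 h correlated at r = 0.815 (77.9% with the same sign) across genes, which are not independent replicates. Both effects carry the genotype difference in 3' bias. With the covariate, whose slopes both times share, r was 0.788 (77.7%). With KO 6 h replicate 2 against the uncorrected 12 h effect it was 0.519 (65%). Both times, which share no array, called 2055 genes in the same direction (1440 higher, 615 lower), where independent lists would share 708. In the average, Il23a alone of the IL-12 family passed (0.46 ± 0.18, adjusted p = 0.0487, and 0.108 adjusted over the list alone). With the covariate it had 0.997 ± 0.402 but did not pass (adjusted p = 0.188), and Il12a passed as lower (−1.24, adjusted p = 0.0301). Camera called 0 of 21 lists, with 5 at an unadjusted p under 0.05, and 1 without KO 12 h replicate 3. With the covariate it called the oligodendrocyte list (9.12e-06, adjusted p = 0.0826 with an estimated correlation) and cholesterol synthesis (0.0491, adjusted p = 0.25 with an estimated correlation). The median log2 fold change of all genes was 0.17, and 0.43 with scaling to a common median, which moved the share of calls that were higher from 62.7% to 75.5%. The median, the mean and the direction of camera differed in sign for 11 of the 21 lists.

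The comparison of 12 h with 6 h in WT asks which mRNAs differ after longer exposure with TLR2 present. Without unexposed arrays the bacteria and time in culture are not separated. Csf2, the granulocyte and macrophage growth factor, was at least 6.06-fold lower at 12 h, Ifnb1 at least 3.94-fold, Serpina3g, a protease inhibitor, at least 6.24-fold, and its paralogue Serpina3f (−3.57 ± 0.22, above background on 1 of 3 arrays at 12 h), the vasoconstrictor Edn1 (−3.18 ± 0.16), Il10 (−2.56 ± 0.19) and Cish (−2.55 ± 0.16) fell. Cyp51, a demethylase of cholesterol synthesis, also fell (−3.98 ± 0.31). Spic, a transcription factor of iron-recycling macrophages, rose at least 3.76-fold, Adh7 at least 2.20-fold, Ypel3 by 2.68 ± 0.22, Jade1 by 2.52 ± 0.28 (above background on 1 of 3 arrays at 6 h), Abi3 by 2.29 ± 0.28 and Lcn2 by 1.92 ± 0.22. Of 8406 genes 1705 passed by limma, 992 higher and 713 lower, with n = 3 per time. Array weights gave 3724 genes, and a required 2-fold change 725. With the index as a covariate 2453 passed, and all 1705 were among them in the same direction. Without WT 6 h replicate 3 the count was 1131, and without WT 12 h replicates 1, 2 and 3 in turn it was 1113, 950 and 1015. The median log2 fold change of all genes was 0.06, and 0.38 with scaling to a common median, which moved the share of calls that rose from 58.2% to 89.1%.

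Camera called 9 lists in WT over time, 8 lower and 1 higher at 12 h. Lower were negative regulators of inflammation (adjusted p = 1.41e-06, 12 of 19 genes fell), type I interferon genes (2.11e-06, 12 of 34), cytokines (2.65e-05, 11 of 23 fell and 3 rose), cholesterol synthesis (2.65e-05, 8 of 14), the cell cycle (0.00121, 7 of 19 fell and 1 rose), toll-like receptor signalling (0.00121, 10 of 26), bacterial sensors (0.00274, 2 of 20) and microglia identity (0.0402, 5 of 22). Examples were Oas1a (−1.51 ± 0.18), Rel (−2.58 ± 0.28), Map3k8 (−1.19 ± 0.22), the sterol reductase Hsd17b7 (−1.79 ± 0.18), Plk1 (−1.91 ± 0.23), Ccnb1 (at least 4.65-fold lower), Cd180 (−1.19 ± 0.17), Tlr3 (−1.41 ± 0.32), Cd33 (−0.98 ± 0.14) and Trem2 (−0.78 ± 0.17). The integrated stress and unfolded protein response was higher (0.00634), where 9 of 21 genes rose and 1 fell, with Trib3 (1.99 ± 0.15) and Chac1 (2.17 ± 0.25, above background on 1 of 3 arrays at 6 h) among them. Plk1 was above background on 2 of 3 arrays at 12 h. Counts adjusted over the list alone were 13 lower negative regulators, 12 lower and 3 higher cytokines, 9 lower and 1 higher cell cycle genes, 5 lower and 2 higher microglia genes, and 14 higher and 3 lower stress genes, and did not differ for the other 4. Sensors had an adjusted p = 0.1 with an estimated correlation and microglia identity an adjusted p = 0.222 with an estimated correlation, and the other 7 calls held. Microglia identity also missed the threshold with the index as a covariate (0.0939) and without WT 6 h replicate 2 (0.1) or 3 (0.0502) or WT 12 h replicate 1 (0.0501) or 3 (0.052). Antigen presentation passed without WT 6 h replicate 1 (0.0394), and the respiratory chain without WT 6 h replicate 2 or 3 (0.0179 to 0.0413). Tlr3 missed the threshold without WT 12 h replicate 2 (−1.31). For phagocytic receptors and the lysosome, not called, the median, the mean and the direction of camera differed in sign.

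Further genes moved without a call for their list in WT. Effectors rose in 8 and fell in 4 of 31 genes, with Lcn2 up and the pattern recognition protein Ptx3 down (−1.95 ± 0.20). Cxcl2 fell (−1.05 ± 0.20) and Ccl5 rose (0.56 ± 0.14), and Cd40 (−1.26 ± 0.14) and Cd86 (−1.39 ± 0.17) fell. Mrc1 (−1.81 ± 0.20) and Gas6 (−1.53 ± 0.19) fell, the cholesterol exporter Abcg1 rose (1.78 ± 0.39, above background on 1 of 3 arrays at 6 h) and Pparg fell (−1.20 ± 0.27), Nqo1 rose (2.12 ± 0.33), and the survival gene Bcl2a1d fell (−1.15 ± 0.19). Smaller changes were seen for Tpi1 (0.73 ± 0.14), Ndrg1 (−0.97 ± 0.29), Ndufs3 (0.55 ± 0.16), Ctsz (0.82 ± 0.18) and Ctsl (−0.94 ± 0.23). Among markers of other cells, Slc1a2 (1.91 ± 0.26), Dcn (2.11 ± 0.20) and S100a8 (0.84 ± 0.17) rose, and Slc1a3 (−0.94 ± 0.15), Cspg4 (−0.64 ± 0.20), Map2 (−0.90 ± 0.20), Dcx (−0.75 ± 0.17), Flt1 (−1.77 ± 0.15) and F13a1 (−1.65 ± 0.26) fell. At 12 h Flt1 and F13a1 were above background on 1 of 3 arrays, and Ndrg1 and Cspg4 on 2 of 3. Calls that ended with 1 array left out were those of Cspg4 (any 1 of 9 arrays, −0.74 to −0.48), Ndrg1 (any 1 of 6, −1.09 to −0.85), Ndufs3 (any 1 of 6, 0.43 to 0.58), Ctsl (WT 12 h replicate 1 or 2, −0.94 to −0.88), Ccl5 (WT 12 h replicate 2 or 3, 0.55 to 0.56), Map2 (WT 12 h replicate 2, −0.83) and Dcx (WT 12 h replicate 3, −0.71). The bias index of the WT arrays differed by 0.15 between the times (exact permutation p = 0.1).

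In KO microglia many of the same genes moved from 6 to 12 h. Spic rose at least 4.43-fold (log2 fold change −0.06 with a probe at nt 399), Adh7 at least 2.97-fold, the prostaglandin receptor Ptger2 at least 5.97-fold, Abi3 by 3.30 ± 0.31, Lcn2 by 2.74 ± 0.25 and Trib3 by 1.95 ± 0.16, while Eid3 (−4.43 ± 0.21), Csf2 (−2.49 ± 0.26), Cyp51 (−2.91 ± 0.35), Cxcl2 (−1.84 ± 0.23) and Nfkbiz (−1.46 ± 0.20) fell. Each of these 11 genes also passed with the index as a covariate, with Aqp9, a glycerol channel (2.86 ± 0.28, above background on 1 of 3 arrays at 6 h), P2ry13 (1.31 ± 0.18), Osgin1 (1.54 ± 0.19), Oasl1 (1.41 ± 0.21, and −0.19 with a probe at nt 901), Lpl (−1.07 ± 0.17), Flt1 (−1.22 ± 0.17), S100a8 (1.06 ± 0.19) and Mrc1 (−0.75 ± 0.23). The falls of Trf (−4.41 ± 1.12), Lcp1 (−4.33 ± 0.98), Fam20c (−4.27 ± 1.0) and the complement gene C1qa (−3.91 ± 1.06) had −0.93, −1.47, −1.07 and −0.27 with the covariate and adjusted p of 0.335 to 0.716, and ended without KO 12 h replicate 3 (−2.63, −2.47, −3.31 and −2.95), those of Trf (−3.84) and C1qa (−3.62) also without KO 6 h replicate 1. Mrc1 missed the threshold with any 1 of 8 arrays left out (−0.90 to −0.60). Abi3 was above background on 2 of 3 arrays at 6 h, and C1qa and Lcp1 on 1 of 2 at 12 h. Of 8406 genes 2009 passed by limma, 1415 higher and 594 lower, and 491 with the covariate (312 higher, 179 lower). Array weights gave 3788 genes, median scaling 3187, a required 2-fold change 1129 and only the 2 groups compared 310. Of the 8406 genes 338 passed without KO 12 h replicate 3, and 1093, 1317 and 3313 without KO 6 h replicates 1, 2 and 3 in turn. The median log2 fold change of all genes was 0.14, and 0.50 with scaling to a common median, which moved the share of calls that rose from 70.4% to 88.0%. WT and KO shared 841 calls in the same direction, 633 higher and 208 lower, where 217 would be shared by independent lists, and the time effects correlated across genes at r = 0.516.

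Camera called 6 lists in KO over time, all lower at 12 h. They were cholesterol synthesis (adjusted p = 0.000121, 6 of 14 genes fell), lipid handling (0.00213, 5 of 16 fell and 1 rose), negative regulators (0.00213, 5 of 19 fell and 1 rose), cytokines (0.00451, 8 of 23 fell and 2 rose), toll-like receptor signalling (0.00451, 5 of 26 fell and 2 rose) and microglia identity (0.00451, 5 of 22 fell and 2 rose). None of the 6 passed with an estimated correlation, where the lowest value was an adjusted p = 0.0551 with an estimated correlation. With the index as a covariate camera called cholesterol synthesis (8.5e-06, and adjusted p = 0.0353 with an estimated correlation), cytokines (0.0039, and adjusted p = 0.0901 with an estimated correlation) and negative regulators (0.00451, and adjusted p = 0.0901 with an estimated correlation). Adjusted over the list alone the falls were 8, 6, 5, 9, 8 and 9 and the rises 0, 1, 1, 4, 4 and 2. Other named changes were Nfkb1 (−1.47 ± 0.25), Nod1 (0.59 ± 0.18), Tap2 (1.11 ± 0.21), Fcgr1 (1.37 ± 0.22), Hk3 (0.65 ± 0.17), Top2a (−1.86 ± 0.37), Ctsl (−1.27 ± 0.25), Bid (1.37 ± 0.24), Slc1a2 (1.71 ± 0.29) and Dcn (at least 1.44-fold higher), and these 10 missed the threshold with the covariate. Their values there were −1.16, 0.43, 1.03, 0.94, 0.63, −1.05, −0.80, 0.69, 1.12 and 1.09 in turn. Top2a and Ctsl were above background on 1 of 2 arrays at 12 h. Without KO 12 h replicate 3 the calls of Tap2 (1.06), Top2a (−1.16), Ctsl (−1.23) and Bid (1.17) ended, that of Hk3 ended without KO 6 h replicate 2 or KO 12 h replicate 1 or 3 (0.52 to 0.78), and that of Nod1 with any 1 of 8 arrays left out (0.56 to 0.60). Camera also called the cell cycle without KO 12 h replicate 3 (0.0446), and glycolysis and hypoxia without KO 6 h replicate 3 or KO 12 h replicate 1 (0.0225 to 0.0484). For phagocytic receptors, the respiratory chain, the lysosome and astrocyte markers, not called, the median, the mean and the direction of camera differed in sign.

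The KO effect itself differed between 12 h and 6 h for 50 genes by the interaction test of limma, 47 with a higher and 3 with a lower KO effect at 12 h, and 1438 genes had an unadjusted p under 0.05. The count depended on the processing, with 1920 genes with array weights, 108 without a filter, 86 with trend and robust settings, 32 with the authors' values, 26 with the replicate block and 18 with median scaling. Hdc, which makes histamine, was lower in KO at 6 h (8.15 ± 0.13 in KO and 10.27 ± 0.20 in WT, n = 3 each) and higher at 12 h (10.13 ± 0.38, n = 2, and 8.97 ± 0.17, n = 3), a difference of 3.28 ± 0.28 (adjusted p = 0.00121). Serpina3f (2.95 ± 0.32), Serpina3g (2.63 ± 0.30), Cish (2.21 ± 0.24) and Il10 (2.10 ± 0.28) fell in WT from 6 to 12 h while their KO levels changed less, and Plk1 (2.35 ± 0.34) and Fas (1.33 ± 0.24) also had differences above 0. These genes passed with the index as a covariate, where 20 genes were called, except Fas (1.03, adjusted p = 0.101). The KO effect of Fas was −0.01 at 12 h with the probe used, at nt 1099, and −2.88 with that at nt 394. Of the 47 genes 23 fell with time in WT and 30 rose in KO. The count was 33 and 14 without WT 6 h replicates 1 and 3, 8, 6 and 17 without WT 12 h replicates 1, 2 and 3, 18 and 1093 without KO 6 h replicates 1 and 3, and 272 and 3 without KO 12 h replicates 1 and 3. Serpina3f and Serpina3g missed the threshold without KO 12 h replicate 3 (2.78 and 2.42), Il10 without WT 12 h replicate 1 or 2 or KO 12 h replicate 3 (2.11 to 2.22), Plk1 with any 1 of 6 arrays left out (2.08 to 2.41) and Fas with any 1 of 9 (1.21 to 1.38). Serpina3g was not above background on any WT array at 12 h.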

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

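The tests of 3' bias and of a lower share of microglia were chosen after the results had been seen, and the tests on other splits of the arrays and on a second oligodendrocyte list before.

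The genotypes differed in many genes, and KO arrays also had a higher 3' bias index. With the index as a covariate 1419 genes still passed at 6 h, which argues against a straight-line 3' bias as the whole cause there. A curved one was not tested. The median absolute log2 fold change of the 2876 calls fell from 1.08 to 0.76 (median SE 0.222 and 0.285) and 98.0% kept their sign. At 12 h 68 of 8406 genes passed. The median absolute change of the 3878 calls went from 1.24 to 0.46, the median SE from 0.269 to 0.469, and 66.9% kept their sign. So calls ended through a smaller or turned change and a larger error. In simulated data with straight-line 3' bias and no genotype effect 0 genes were called at 6 h and 4720 at 12 h. With changed genes the covariate fit recovered 85 and 40 of 100 changed 4-fold and 26 and 1 of 100 changed 2-fold. So 3' bias and genotype cannot be told apart for most calls at 12 h, and RNA quality may account for many of them. Averaged over both times, 1 of 100 drawn splits of the arrays within each time, the real one, gave as many as 4696 genes. This share lies under 0.05 and argues against a chance split of these arrays. The highest other split gave 2950 by exchanging KO 6 h replicate 2 with a WT array. Because the index also differs between the genotypes, the splits cannot tell genotype from 3' bias.

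Oligodendrocyte lineage markers were higher on KO arrays, with a mean difference of 2.00 ± 0.08 (SE, 7 genes) at 6 h, or 1.87 with 3 members set at their bounds. With the index as a covariate the difference was 2.03 (SE 0.129), which argues against straight-line 3' bias as its cause. A lower share of microglia need not raise every marker list. In the same fit neuron markers had 1.16 (SE 0.215) and astrocyte markers −1.05 (SE 0.151). The 2 fibroblast markers had −1.99 (SE 0.229), a difference of 4.02 (SE 0.263) from the oligodendrocyte ones. This argues only against a rise of all other cell types. Of 11 measured genes of a second oligodendrocyte list of 36, 5 were higher on all 5 KO than on all 6 WT arrays (Ugt8a, Nkx2-2, Enpp2, Sox8 and Omg), short of the majority set as the bound beforehand, and these had WT means of 4.71 to 5.88, so their signal in KO helped them pass the detection filter and the test decides nothing. More oligodendrocyte-lineage cells in the KO cultures may be a source of these transcripts, as may a change within such cells, and both stay open. Mbp had a mean log2 intensity of 10.20 in KO and 5.80 in WT at 6 h (probe at nt 2211). Its probe at nt 4610 gave a log2 fold change of −0.28.

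The splits of 3 arrays against 3 are too few for a share under 0.05. For KO against WT at 6 h, 1 of 10 splits gave as many genes as the 2876 found, and the highest other split gave 0. For time in WT, 1 of 10 gave as many as the 1705 found, and the highest other split gave 0.

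The KO effect differed between 12 h and 6 h for 50 genes by the interaction test of limma (18 with median scaling and 1920 with array weights), and this difference is what brings the following genes here. Hdc, which makes histamine, had a difference of 3.28 (−2.12 at 6 h and 1.16 at 12 h, adjusted p = 0.00121). The protease inhibitors Serpina3f and Serpina3g had 2.95 (adjusted p = 0.00466) and 2.63 (adjusted p = 0.00562). Gbp7, an interferon-induced GTPase, had 2.75 (−1.35 and 1.40, adjusted p = 0.0182). Lad1 had 2.75 (adjusted p = 0.0111), with 0 of 3 WT arrays above background at 12 h and 1 of 3 KO arrays at 6 h. Cish had 2.21 (−0.42 and 1.80, adjusted p = 0.00466). Il10 had 2.10 (−2.18 and −0.08, adjusted p = 0.0104). The cytokine Il15 had 1.74 (0.37 and 2.11, adjusted p = 0.0252, and −1.59 and −1.81 with a probe at nt 90), and Oasl1 1.72 (−1.07 and 0.65, adjusted p = 0.0246, and −4.39 and −3.48 with a probe at nt 901). The mitotic kinase Plk1 had 2.35 (−1.72 and 0.64, adjusted p = 0.0152), and the death receptor Fas 1.33 (−1.35 and −0.01, adjusted p = 0.0374, and −1.77 and −2.88 with a probe at nt 394, a difference of −1.11). Ypel3 had −1.99 (0.84 and −1.15, adjusted p = 0.0297). The histone demethylase Kdm4a had −1.75 (adjusted p = 0.0413), above background on the 3 KO arrays at 6 h and on 0 other arrays. Siglece, an inhibitory receptor for sialic acid, had −1.19 (adjusted p = 0.0364), above background on the 3 WT arrays at 12 h and on 0 others. The differences of Serpina3g, Lad1, Kdm4a and Siglece, each with a group not above background, are fitted values and no bounds. Of these 14 genes Hdc, Serpina3f, Serpina3g, Lad1, Kdm4a, Cish, Il10 and Plk1 also passed with the index as a covariate. Hdc and Cish passed with each array left out in turn, and the other 12 missed the threshold without at least 1 array. Without KO 12 h replicate 3 all 12 missed it. Among the 3 genes below 0, 2 rose in WT and 1 fell in KO. No group held the 4 arrays that the rule used here asks for, so no test for a single outlying array was run.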

How the results depend on the processing

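The 3' bias covariate and the fit of the WT arrays with KO 6 h replicate 2 were chosen after the data had been seen, and the estimator of the array weights was changed to the gene-by-gene one after the default had not converged and its counts had been seen. All other alternatives were fixed beforehand. Of 265 values of named genes, direction and side of the threshold were kept by 263 of 263 under the stricter filter, 264 with array weights, 261 with trend and robust settings, 261 with offset 50, 258 without background correction, 256 without a filter, 256 with the replicate block, 247 with the mean of probes, 239 with the authors' values, 229 with median scaling and 166 with the bias covariate. They were kept by 228 of 251 with only the 2 groups compared, 132 of 152 with KO 6 h replicate 2 and 2723 of 2915 with 1 array left out, where 190 lost the threshold. Genes near background and probes that part along a transcript limit single values. The cause of a change below was not tested unless named.

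With the bias covariate the counts of genes were 1419 (KO against WT at 6 h), 68 (12 h), 513 (average), 491 (time in KO) and 20 (difference of KO effects), with 2 IL-12 family genes at 6 h, where Il12a passed at −0.84, and camera called 2 lists in the average and 3 for time in KO. Its index is higher in KO, and KO effects shrank or grew with larger median errors. It reversed Apoc2 at 6 h (0.22) and at 12 h Hspa8 (0.58), Msn (0.83), Ifit3b (0.83), Pld3 (0.016), Eif4g2 (1.15), Eno1 (0.29), Tlr8 (1.39), Tnfsf9 (0.10), Isg15 (0.013), Mfge8 (0.055), Adm (−0.18), Atp5o (1.01), Nsdhl (0.59), Tyms (0.14), Bcl2l1 (0.997) and Cspg4 (0.027). With KO 6 h replicate 2, a smaller group, 1466 genes and 2 lists passed at 6 h, the oligodendrocyte list (0.000984) and cholesterol synthesis (0.0463), each with an adjusted p = 0.375 with an estimated correlation.

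With array weights 4680 genes passed at 6 h, 3724 for time in WT, 3788 for time in KO and 1920 for the difference, the correlation of KO effects was 0.732, and 2 IL-12 family genes passed at 6 h, with Il27 at 0.63. A required 2-fold change left, by construction, 1602 genes at 6 h, 2507 at 12 h, 2046 in the average, 725 for time in WT and 1129 for time in KO. Only the 2 groups compared, with fewer arrays, gave 310 genes for time in KO and 4 lists at 6 h. Median scaling gave 3187 genes for time in KO, 18 for the difference and 3 lists at 6 h. The authors' values gave 32 genes for the difference and 8, 3, 7, 16 and 14 lists at 6 h, at 12 h, in the average, for time in WT and for time in KO, and turned the median of the effectors for time in WT to −0.047. No filter, with more genes tested, gave 108 genes for the difference and 5, 3 and 2 lists at 6 h, 12 h and in the average. Trend and robust settings gave 86 genes for the difference. The replicate block gave 26 genes for the difference and 0 lists at 6 h. Of 15 same-numbered pairs of arrays 5 had a correlation of residuals over 0.1 (range −0.26 to 0.58), so the numbers were not read as pairs.

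Lists called at 6 h and in the average were 5 and 4 without background correction, 4 and 4 with offset 50 and 4 and 4 with the mean of probes, and 3 at 6 h with the stricter filter. With an estimated correlation camera called 0 lists at 6 h, 0 at 12 h and 0 for time in KO. Fry, which does not compare a list with other genes, called 12, 17, 16, 14 and 10 lists at 6 h, at 12 h, in the average, for time in WT and for time in KO. Its direction was opposite to that of camera for chemokines at 6 h (median −0.092) and at 12 h for bacterial sensors (0.26), signalling (0.076), negative regulators (0.17), cytokines (0.0058) and oxidative stress (−0.0035), and in the average for signalling (0.044), chemokines (−0.043), interferon genes (0.088), the cell cycle (0.23) and the lysosome (0.013). The mean of probes reversed Marcksl1 (−1.44 at 6 h and −1.93 at 12 h), Csf1r (−0.83 and −1.94), Mlkl at 6 h (0.44) and Sqle at 12 h (−0.041), each with probes of opposite sign.

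With 1 array left out, where a lone array is assumed to vary like the other groups, counts ranged from 2160 to 3365 at 6 h, 1715 to 4355 at 12 h, 3653 to 4958 in the average, 950 to 2236 for time in WT, 338 to 3313 for time in KO and 3 to 1093 for the difference. The correlation of KO effects ranged from 0.664 to 0.867. Lists ranged from 0 to 4 at 6 h, 0 to 3 at 12 h, 0 to 1 in the average, 8 to 10 for time in WT and 6 to 7 for time in KO. IL-12 family counts stayed at 1 at 6 h and 0 at 12 h. Log2 fold changes at 6 h and 12 h ranged from −0.43 to 0.07 and −0.54 to −0.25 for Il12a, 0.13 to 0.64 and −0.30 to 0.99 for Il27, and −0.27 to 0.07 and −0.29 to −0.22 for Ebi3. The planned chip block was not run, since the files give no chip identifiers.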

Other observations

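The genes and probes described were chosen after their values had been seen, except in the test of genes near Tlr2, which was written before its result was seen.

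Some genes that no fixed list held differed between the genotypes at both times, also with the bias index as a covariate, where 66 genes passed at both times (32 higher and 34 lower in KO). Lower in KO were 4 named Ear genes, which encode eosinophil-associated ribonucleases. Ear2 had −3.38 ± 0.19 at 6 h and −3.93 ± 0.21 at 12 h, and Ear4 −3.53 ± 0.22 and −3.78 ± 0.24. Ear10 had −1.58 ± 0.29 and −1.32 ± 0.32, and Ear12 −1.58 ± 0.27 and −0.96 ± 0.30, both above background on 2 of 3 KO arrays at 6 h. These paralogues are so alike that the probes need not separate them. Also lower were Timp1, an inhibitor of metalloproteinases, at −3.17 ± 0.26 and −3.40 ± 0.29, the collagen crosslinking enzyme Lox at −1.73 ± 0.19 and −2.08 ± 0.21, and Tgfbi at −1.58 ± 0.14 and −1.79 ± 0.16.

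Further genes were higher in KO at both times. The glutamate receptor subunit Gria2 had 2.35 ± 0.17 at 6 h and 2.57 ± 0.19 at 12 h, the brain creatine kinase Ckb 0.87 ± 0.14 and 1.88 ± 0.16, the tubulin Tubb2b 1.31 ± 0.32 and 1.73 ± 0.35 (−0.42 and −1.45 with a probe at nt 1176), and Tril, a co-receptor of toll-like receptors found in brain, 2.48 ± 0.20 and 3.16 ± 0.22. The tubulin-binding protein Stmn1 was at least 4.77-fold higher at 6 h and at least 5.05-fold at 12 h. Tmem176b had 3.13 ± 0.17 and 3.23 ± 0.19, and the stress cytokine Gdf15 2.39 ± 0.19 and 2.40 ± 0.21. These genes, and the lower ones named before them, kept direction and passed the threshold at both times without background correction, with scaling to a common median, with the authors' values, without a filter and with the covariate.

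The TLR2 knockout was bred onto the WT strain, so genes beside Tlr2 may come from the strain in which the gene was first deleted. If that changed their mRNA, the share of calls near Tlr2 would exceed that of other genes. Within 10 Mb of Tlr2, 7.5% of genes (6 of 80) passed in the average of both times with the bias index as a covariate, against 6.14% of the others (one-sided Fisher's exact p = 0.371). At 6 h with the covariate it was 15% against 17.1% (Fisher's exact p = 0.735), and without the covariate 41.3% against 33.6% at 6 h (Fisher's exact p = 0.0947) and 63.8% against 55.2% in the average (Fisher's exact p = 0.0764). The test left the question open, since a share this close to that of other genes excludes no single gene. Sema4a, a semaphorin among the 6, had −2.52 ± 0.14 at 6 h and −2.12 ± 0.16 at 12 h.

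Probes of Actb, the beta-actin transcript, show how far probes within a transcript can part on these arrays. The probe at nt 14 ranged from 8.02 to 14.6 normalized log2 units over the 11 arrays and was lowest on KO 12 h replicate 3. The probe at nt 1610 ranged from 14.0 to 15.5 and was highest on the same array. Probes at nt 1408 and 1412 ranged from 4.63 to 15.4 and from 4.70 to 15.6, and were below 6 on WT 6 h replicate 2, on WT 12 h replicates 2 and 3 and on KO 6 h replicate 2.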
